A study of Homo sapiens with 8 samples.

How the data were processed

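The series deposited 1 gene table per library, 8 in all, with an expected count, a TPM value and an effective length for each of 23686 gene symbols. The submitters' processing notes name FastQC for read quality, RSEM 1.2.12 for quantification and build hg19, and total RNA was prepared with a Qiagen RNeasy mini kit. The expected counts, as deposited by the authors, were RSEM's estimates of reads per gene, with reads that fit several genes shared out among them. The TPM values, per the file headers and as deposited, were the same estimates divided by effective length and scaled to a fixed total. The aligner and any trimming are not given in the sources used here. Between 96.5 and 96.6% of the detected expected counts were whole numbers, and all were rounded. Groups were read from the sample titles. The genotype tag calls the depleted samples knockouts while their titles name an siRNA, the cell line tag is constant within a line while the source label counts upward from sample to sample, and the cell line tag was used. The type of control and the number of siRNAs are not stated.

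Genes were kept by edgeR's filterByExpr with the 4 groups, which left 14249, scaled by TMM factors and fitted with a mean per group on all 8 libraries (4 residual degrees of freedom). Comparisons were tested with edgeR's quasi-likelihood test and called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Standard errors are the absolute log2 change over the square root of the F statistic, which understates the error of large changes such as that of GPX1. The design, the rule for naming genes, the alternative settings and 32 gene lists were fixed before the data were examined. Of the lists, 31 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each comparison, and repeated with a correlation estimated per list and with fry. The other list, of mitochondrially encoded genes, had 0 members in the files. At an unadjusted p under 0.05 with the estimated correlation, 1, 0, 2 and 4 lists passed in Hs578T, MDA-MB-231, the interaction and the controls, and 0 passed with adjustment, against 22, 17, 11 and 31 by fry with adjustment. With the estimated correlation the matrix genes did not pass in the controls either, although 35 of 41 were higher in Hs578T. Failing it therefore does not show that a list was unchanged.

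The named genes were GPX1 and, for each line, the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 5 CPM over the line's 4 libraries and had both depleted libraries on the same side of both controls. For genes changed in both lines the 8 per direction with the largest smaller change were named, for the interaction 5 per direction with at least 5 CPM in a line, for the controls 8 per direction with at least 20 CPM in the higher line, and for each list up to 4 members by smallest p. Symbols of uncharacterised loci and of small RNAs were passed over. SMN1 was named after its values were seen. Some list members that the rule names are not reported. Where a group held 0 counts, the stated folds used a floor of 3 counts over the group and left out counting error in the other group. List medians and differences between the lines are fitted values.

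The search of 3′ UTRs was added after the fold changes had been seen. Transcript sequences of GENCODE 29 were joined by accession or gene symbol, and only their sequences were used, since that release is on a later build than the files. Of the tested genes, 13147 (92.3%) had a 3′ UTR of at least 30 bases, and each of 16225 sequences of 7 bases was tested by a linear model of the log2 change with Bonferroni adjustment. GPX1 was left out of the classes of matched genes.

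The pipeline was tried on counts simulated from these libraries with 50 genes seeded at each size of change. Changes of 1.25-, 1.5-, 2- and 4-fold were recovered for 54, 86, 88 and 100% in Hs578T and for 66, 82, 94 and 98% in MDA-MB-231, with 8.45 and 8.97% false calls. A list lowered by 0.3 on the log2 scale passed, with 0 other lists. It also passed with the estimated correlation (adjusted p = 0.0234 in Hs578T and 0.00785 in MDA-MB-231 by camera). Genes were drawn independently, so these runs cannot show how the list tests behave where members are correlated. A sequence of 7 bases given an effect ranked 1 of all, with 0 past Bonferroni adjustment once the changes were shuffled. The alternatives were DESeq2 size factors in edgeR, DESeq2 and limma-voom, no filter and a stricter one (5 CPM in 2 libraries), each line fitted alone, replicate number as a block (2 residual degrees of freedom), a test against a fold of 1.5, limma on log2(TPM + 1), and each library left out. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.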

Results

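Gene expression was measured by RNA sequencing in 8 libraries from a pair of human triple-negative breast cancer cell lines, Hs578T and MDA-MB-231, which lack the receptors that define the other breast cancer classes. Each line was sequenced as a control and after depletion of GPX1, the glutathione peroxidase that reduces hydrogen peroxide in the cytosol and mitochondria, with 2 libraries in each of the 4 groups. The depleted libraries carry an siRNA prefix in their titles and are called siGPX1 here. The study's title links GPX1 to metastasis of this cancer, and the comparisons ask how the transcriptome of each line differed after GPX1 depletion. The libraries held 12905808 to 14216365 estimated counts each and detected 15584 to 15817 of 23686 listed genes, of which 14249 were tested. Nothing in the labels says that the replicates were separate cultures. The p-value of a gene therefore measures only the spread between these libraries, which may be technical. That spread was small, with a biological coefficient of variation of 0.0341, and a large number of small changes passed the test. P-values from linear models across genes rest on the spread among genes instead. These and the list tests use the same libraries, so neither is known to cover the spread between cultures.

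GPX1 fell to a few percent of its control level in both lines. In Hs578T it went from 84.1 ± 0.121 CPM (counts scaled to a fixed library total; mean ± SD, n = 2) to 3.49 ± 0.107, and in MDA-MB-231 from 201 ± 10.5 to 7.03 ± 0.351. The 4 control libraries held 1117, 1074, 2944 and 3223 GPX1 counts and the 4 siGPX1 libraries 42, 42, 108 and 95, so every library lay on the side its label gives. The remaining level was 4.16% of control in Hs578T and 3.50% in MDA-MB-231. Adjusted p was 1.52e-14 and 9.5e-16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the size of the fall did not differ detectably between the lines (difference of -0.25 on the log2 scale, adjusted p = 0.41 by the same test).

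**Figure D1:**
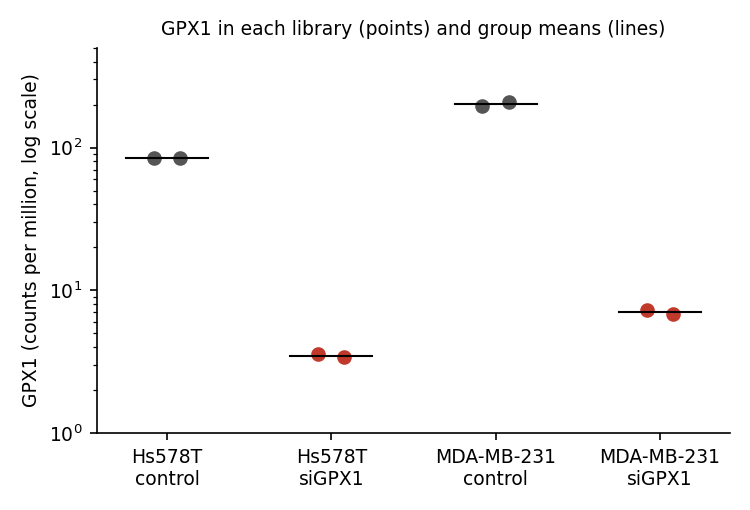
GPX1 level in CPM on a log axis, for the 8 libraries by group; points are libraries and lines are group means. The siGPX1 libraries of Hs578T and MDA-MB-231 lie near 3.49 and 7.03, against control means of 84.1 and 201.

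Genes whose 3′ untranslated region (UTR) matched one stretch of the GPX1 transcript had lower medians after depletion in both lines. Of 1822 such genes, 43.7% fell and 17.3% rose in Hs578T and 44.1% fell and 13.4% rose in MDA-MB-231. Among 16225 sequences of 7 bases searched in the 3′ UTRs of tested genes, GGGCATC and GGCATCA had the strongest association with lower expression in each line, with Bonferroni-adjusted p of 4.96e-65 and 1.07e-53 in Hs578T and 3.23e-76 and 5.1e-80 in MDA-MB-231 from linear models across genes, which are not independent replicates. Together they form GGGCATCA, a sequence found in 3 of 4 annotated GPX1 transcripts. The 316 genes with the whole 8-base sequence had a median log2 fold change of -0.39 in Hs578T and -0.36 in MDA-MB-231, the 1506 genes with only a 7-base match had -0.16 and -0.19, and the 11324 genes with neither had 0.07 and 0.01. Named genes with at least one of these 7-base matches in their 3′ UTR are called matched here. ACTTCGA and TACTTCG went with higher expression, and genes with either are called control-matched.

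**Figure D2:**
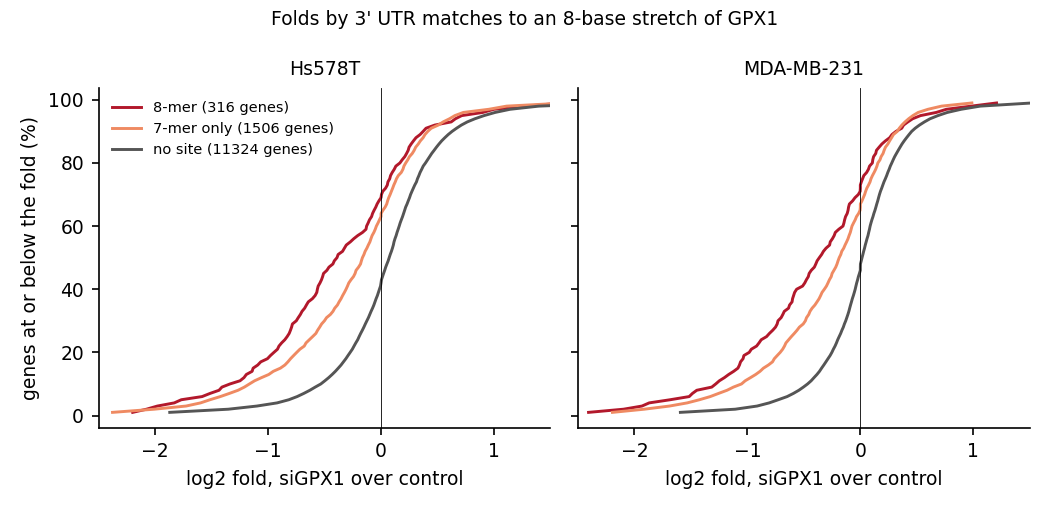
Percentage of genes (vertical axis, %) at or under a given log2 fold change of siGPX1 over control (horizontal axis), in Hs578T (left) and MDA-MB-231 (right), drawn from percentiles 1 to 99; each line is a class of genes by 3′ UTR match to GGGCATCA. The curve for the 316 genes with the 8-base match lies to the left of that for the 11324 genes without a match, with medians of -0.39 against 0.07 and -0.36 against 0.01.

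In Hs578T, GPX1 depletion went with higher CEBPD, SCG2, CCDC71L, TNFRSF11B and MUC1 and with lower LMO2, CX3CL1, CLCN4 and MDH2. CEBPD, a transcription factor of the acute-phase response, rose 9.54-fold, from 10.5 to 100 CPM (log2 change 3.25 ± 0.10, SE). SCG2, which encodes the secretory granule protein secretogranin II, rose 8.66-fold, TNFRSF11B, the decoy receptor osteoprotegerin, 4.74-fold, and MUC1, a membrane mucin, 4.71-fold. LMO2, a transcriptional cofactor of blood cell development, fell 11.5-fold, CX3CL1, the chemokine fractalkine, 8.22-fold, CLCN4, a chloride/proton exchanger, 7.99-fold, and MDH2, the mitochondrial malate dehydrogenase, 7.34-fold, from 164 to 22.3 CPM. In all, 4074 genes rose and 3154 fell, of which 395 and 522 changed over 2-fold. The excess of rises was not kept with limma on log2(TPM + 1), which gave 3367 rises and 3563 falls, with the stricter filter (3363 and 3457), with Hs578T fitted alone (3188 and 3350) or without any single MDA-MB-231 library.

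The other genes with the largest rises were NCALD (3.63 ± 0.30 on the log2 scale), CCDC71L (5.65-fold) and the potassium channel subunit KCNE4 (2.24 ± 0.10). Also among them were C1orf151-NBL1, C4A and C4B, whose values are uncertain. C1orf151-NBL1 is a read-through transcript that overlaps its parent genes and held 1 and 0 counts in the controls against 517 and 45 after depletion, and the near-identical complement genes C4A and C4B (2.42 ± 0.24 and 2.21 ± 0.21) share reads. The other large falls were those of SYT11 (-2.56 ± 0.18), the adiponectin receptor ADIPOR2 (-2.53 ± 0.08), the ribosomal protein gene RPS29 (-2.41 ± 0.08), TMEM64 (-2.33 ± 0.10) and the long noncoding RNA FGD5-AS1 (-2.32 ± 0.05). All 20 genes named by size of change in Hs578T had an adjusted p of at most 1.4e-04 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 8 largest falls with a searched 3′ UTR, 5 were matched, namely LMO2, CLCN4, MDH2, RPS29 and TMEM64.

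Among 31 gene lists tested, mitotic genes gave the smallest p in Hs578T. Of 37 G2/M genes, 30 fell and 1 rose (31 fell and 1 rose adjusted over the list alone), among them the topoisomerase TOP2A (-1.89 ± 0.04), the anaphase activator CDC20 (-1.12 ± 0.04), the proliferation marker MKI67 (-0.92 ± 0.04) and the kinesin KIF2C (-0.94 ± 0.04, matched). The list's adjusted p was 1.72e-07 by camera with Benjamini-Hochberg adjustment and a preset correlation, and adjusted p = 0.815 with an estimated correlation. Of 37 genes of the G1/S transition, 19 fell and 5 rose (19 and 6 adjusted over the list alone), including the helicase subunit MCM5 (-1.54 ± 0.05) and the histone mRNA binding protein SLBP (-1.12 ± 0.06, matched), with camera adjusted p = 0.0109 and adjusted p = 0.918 with an estimated correlation. That call was lost without siGPX1 replicate 1 (adjusted p = 0.159 by camera with Benjamini-Hochberg adjustment).

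Hypoxia-inducible genes were the only list that passed with higher expression in Hs578T. Of 26 genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone), with a median log2 change of 0.46, and they included the transcription factor BHLHE40 (1.28 ± 0.04), the angiogenic factor VEGFA (0.91 ± 0.04), the collagen-modifying enzyme PLOD2 (0.84 ± 0.04) and the pyruvate dehydrogenase kinase PDK1 (1.05 ± 0.06). Camera gave adjusted p = 0.00393, and adjusted p = 0.815 with an estimated correlation. Sterol and lipid synthesis genes went down with the same camera adjusted p of 0.00393 (adjusted p = 0.815 with an estimated correlation). Of 29, 14 fell and 2 rose (14 and 2 adjusted over the list alone), with the fatty acid synthase FASN at -0.99 ± 0.04 and FADS2 2.29-fold lower (matched), while INSIG1, which restrains sterol synthesis, rose by 0.71 ± 0.08. FASN and FADS2 act in fatty acid rather than sterol synthesis.

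Interferon and cytokine genes were lower as well in Hs578T. Of 38 interferon-induced genes, 17 fell and 3 rose (17 and 3 adjusted over the list alone), including the antiviral enzyme OAS3 (2.63-fold lower, matched) and IFIT1 (-0.82 ± 0.08, control-matched), with camera adjusted p = 0.0109 and adjusted p = 0.815 with an estimated correlation. Of 27 targets of NF-κB and cytokine genes, 13 fell and 5 rose (13 and 5 adjusted over the list alone). CSF1, the macrophage growth factor, fell by 2.05 ± 0.04 on the log2 scale (matched), CCL2 by 0.81 ± 0.05 and IL8 2.55-fold, whereas IL6 rose by 0.94 ± 0.06. Camera gave this list adjusted p = 0.0364 (adjusted p = 0.855 with an estimated correlation), and the call was lost without any 1 of 6 of the 8 libraries (highest adjusted p = 0.108), with the stricter filter (adjusted p = 0.0709), with TPM values (adjusted p = 0.0811), with the replicate block (adjusted p = 0.0512) and when genes with either pair of 7-base matches or without a searched 3′ UTR were set aside (adjusted p = 0.342). Of 5 metallothioneins, which bind zinc and copper, 4 fell and 0 rose (4 and 0 adjusted over the list alone). MT2A was at -1.10 ± 0.04, MT1E at -1.63 ± 0.11, MT1X at -1.01 ± 0.11 and MT1M at -1.10 ± 0.20, and the list had camera adjusted p = 0.0109 and adjusted p = 0.815 with an estimated correlation. Their near-identical sequences make the split of reads among them uncertain.

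Of 70 cytosolic ribosomal protein genes, 22 fell, 9 rose and 39 did not pass in Hs578T (22 and 9 adjusted over the list alone). RPS29 (-2.41 ± 0.08, matched), RPL8 (-1.84 ± 0.04), RPL14 (-0.82 ± 0.04) and RPL3 (-0.77 ± 0.03) went down, while the list's median was -0.03, and reads of these genes can be shared with their processed pseudogenes. Camera gave adjusted p = 0.0271 (adjusted p = 0.918 with an estimated correlation), a call lost without control replicate 2 or siGPX1 replicate 1 (highest adjusted p = 0.291). Each member that passed among those named for the lists in Hs578T had an adjusted p of at most 0.0361 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lists of markers of other cells did not pass by camera in Hs578T. Fry passed luminal breast markers (3 rose and 1 fell of 15, adjusted p = 0.00136), basal keratinocyte markers (4 and 1 of 8, adjusted p = 0.00691) and endothelial markers (3 and 0 of 6, adjusted p = 0.0398), each upward. The luminal median was 0. Without matched or control-matched genes and those lacking a searched 3′ UTR, the endothelial median went from 0.34 to -0.02. Luminal markers, which include KRT8 and KRT18, took 0.0459 and 0.0465% of control counts and 0.0778 and 0.0844% after depletion. Leukocyte markers stayed near 0 CPM, with 5 of 20 over 1 CPM in both groups, and the 18 fibroblast markers, 16 of them over 1 CPM, had a median of 197 CPM in control and 238 CPM after depletion. FN1, the most abundant transcript of the line, took 3.62 and 3.54% of control counts and 4.87 and 4.39% after depletion, and the 10 most abundant genes together went from 8.77% in both controls to 10.6 and 9.83%. The siGPX1 replicates of Hs578T also differed more from each other than those of any other group, with a mean chi-square per gene of 4.28 against 1.34 to 2.01.

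In MDA-MB-231, GPX1 depletion went with lower IL11, TMEM64, ADIPOR2 and MDH2 and with higher ARL6IP1, SOX4 and CDC42SE2. IL11, a cytokine of the IL-6 family, fell 10.5-fold, from 68.0 to 6.47 CPM (log2 change -3.39 ± 0.10, matched). The transmembrane protein gene TMEM64 fell 8.28-fold (matched), ADIPOR2 6.87-fold and MDH2 5.79-fold (matched). ARL6IP1, an endoplasmic reticulum membrane protein, rose 4.39-fold, from 131 to 574 CPM (log2 change 2.13 ± 0.04), SOX4, a developmental transcription factor, 3.54-fold and CDC42SE2, an effector of the GTPase CDC42, 3.31-fold. In all, 2950 genes rose and 3115 fell, of which 176 and 421 changed over 2-fold. The balance depended on the scaling and the filter, with 3440 rises and 2758 falls with DESeq2 size factors in edgeR, 2304 and 1835 by DESeq2 and 3652 and 2544 with the stricter filter, and falls numbered 2076, 2037 and 2070 without control replicate 2, siGPX1 replicate 1 or siGPX1 replicate 2.

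Further large falls in MDA-MB-231 were those of DENND6A (-2.53 ± 0.07), CLCN4 (-2.47 ± 0.07), the splicing factor gene PHF5A (-2.44 ± 0.13) and TCTA (-2.39 ± 0.10), and further large rises those of the claudin gene CLDN12 (1.65 ± 0.07), the mRNA decapping enzyme DCP2 (1.64 ± 0.05), FAM160B1 (1.56 ± 0.06), C4orf46 (1.55 ± 0.07) and CPOX, an enzyme of heme synthesis (1.55 ± 0.04). SMN2 (2.10 ± 0.20), HERC2P3 (1.65 ± 0.35) and GTF2H2C (-2.46 ± 0.23) also ranked there but have near-identical copies, and their values are uncertain. SMN1, the near-identical partner of SMN2, was at -0.96 ± 0.12. All 20 genes named by size of change in MDA-MB-231 had an adjusted p of at most 0.00125 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 9 largest falls with a searched 3′ UTR, 7 were matched, namely IL11, TMEM64, MDH2, CLCN4, GTF2H2C, PHF5A and TCTA, and of the 9 largest rises SOX4, CDC42SE2, FAM160B1 and C4orf46 were control-matched.

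Cytokine and NF-κB target genes were the only list of 31 that passed in MDA-MB-231 with the preset correlation. Of 27 members, 17 fell and 4 rose (18 and 4 adjusted over the list alone), with a median log2 change of -0.45. The 21 members with a searched 3′ UTR and neither class of match had a median of -0.20, and the list passed with them alone (adjusted p = 0.00896 by camera with Benjamini-Hochberg adjustment). Beside IL11, the falls included IL6 (-1.94 ± 0.07), the neutrophil chemokine CXCL1 (-1.92 ± 0.08) and CSF1 (-1.05 ± 0.04, matched). Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00154, and adjusted p = 0.735 with an estimated correlation. By the rotation test fry, which asks only whether a list's genes moved one way on balance, 17 lists passed in this line and 22 in Hs578T. In MDA-MB-231 they included luminal breast markers (7 rose and 2 fell, adjusted p = 0.00203 by fry). Leukocyte markers (2 rose and 1 fell) and basal keratinocyte markers (1 rose and 0 fell) passed there too, each upward with adjusted p = 0.043 by fry.

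Of the 37 G2/M genes in MDA-MB-231, 15 rose, 9 fell and 13 did not pass (17 rose and 10 fell adjusted over the list alone), and the list did not pass, with adjusted p = 0.48 by camera. TOP2A fell there too (-1.36 ± 0.03), as did KIF2C (-0.52 ± 0.04, matched) and CENPE (-0.39 ± 0.04), and ANLN rose (0.29 ± 0.03). Of the 37 G1/S genes, 17 fell and 4 rose (18 and 4 adjusted over the list alone), with SLBP at -1.02 ± 0.05 (matched) and MCM5 at -0.93 ± 0.06, and the list did not pass (adjusted p = 0.0752 by camera) nor differ detectably from Hs578T (adjusted p = 0.272 for the interaction). Of the 26 hypoxia genes, 7 rose and 8 fell (8 and 8 adjusted over the list alone), with adjusted p = 0.881 by camera, with PDK1 at 0.78 ± 0.07 and NDRG1 at -0.95 ± 0.05 (matched). Sterol and lipid genes showed 13 falls and 1 rise among 29 (13 and 1 adjusted over the list alone), with adjusted p = 0.0752 by camera, with FASN at -0.61 ± 0.04. Each named list member that passed in MDA-MB-231 had an adjusted p of at most 0.0496 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

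The responses of the lines overlapped. Of the genes tested, 2127 rose in both lines against 843 for independent sets of the same sizes, and 2033 fell in both against 690, while 220 passed in opposite directions. Over 2-fold in both lines were 62 rises and 227 falls. Besides GPX1, the largest falls common to both were those of MDH2 (-2.88 ± 0.06 in Hs578T and -2.53 ± 0.05 in MDA-MB-231), ADIPOR2 (-2.53 ± 0.08 and -2.78 ± 0.07), CLCN4 (7.99-fold and 5.54-fold) and TMEM64 (-2.33 ± 0.10 and -3.05 ± 0.09), followed by PHF5A, FGD5-AS1 and the chaperone cofactor gene BAG2, at -2.13 ± 0.07 and -2.14 ± 0.06. The largest common rises were those of ARL6IP1 (2.06 ± 0.05 and 2.13 ± 0.04), CDC42SE2 (1.77 ± 0.07 and 1.73 ± 0.06), CLDN12 (1.69 ± 0.10 and 1.65 ± 0.07) and CPOX (1.67 ± 0.05 and 1.55 ± 0.04), followed by EFR3A, TATDN3, the inositol phosphatase INPP5A and CAV2, which encodes caveolin 2 (2.78-fold and 2.65-fold). The lines did not share control libraries. Across genes, which are not independent replicates, the log2 changes in both lines correlated with Pearson's r of 0.43 and Spearman's rho of 0.59.

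Matched genes made up a large part of the common falls. Of 1971 genes that fell in both lines and had a searched 3′ UTR, 634 (32.2%) were matched, against 1822 of 13146 (13.9%) of all genes searched, and over 2-fold the share was 131 of 218 (60.1%). Among the 8 largest common falls, 6 had a searched 3′ UTR, and MDH2, CLCN4, TMEM64 and PHF5A were matched while ADIPOR2 and BAG2 were not. With genes of either class of match and genes without a searched 3′ UTR set aside, 1325 genes fell in both lines. Among genes that rose in both lines, 109 of 2086 (5.23%) were control-matched, against 341 of 13146 (2.59%) of those searched, and CDC42SE2 and TATDN3 were among them. The 41 genes with the joined 8 bases TACTTCGA had a median log2 change of 0.45 in Hs578T and 0.30 in MDA-MB-231.

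**Figure D3:**
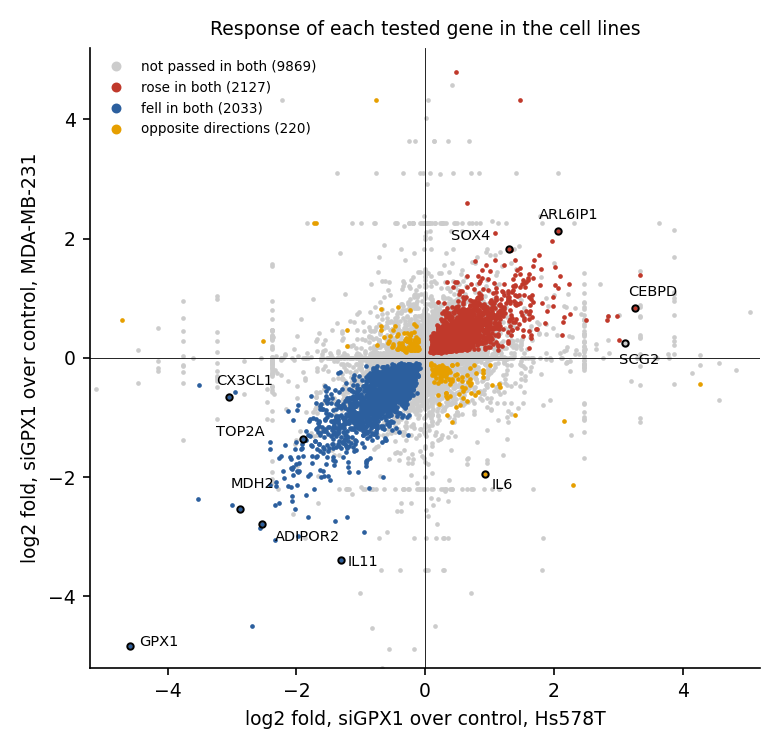
Log2 fold change of siGPX1 over control in Hs578T (horizontal axis) against that in MDA-MB-231 (vertical axis), each point a tested gene coloured by whether it passed in both lines and in which direction; 25 genes lie outside the plotted range. The 2127 genes that rose in both lines and the 2033 that fell in both lie along the diagonal, IL6 is among the 220 with opposite directions, and the horizontal and vertical rows of grey points are genes with a few counts.

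Which genes responded differently in the lines was tested with the interaction of line and depletion. IL6, the cytokine, rose in Hs578T from 47.8 to 91.3 CPM (log2 change 0.94 ± 0.06) and fell in MDA-MB-231 from 92.7 to 24.1 CPM (-1.94 ± 0.07), a difference of -2.88 ± 0.09 with adjusted p = 8.6e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. SCG2 rose in Hs578T and was at 0.25 ± 0.22 in MDA-MB-231, a difference of -2.86 ± 0.26. CX3CL1 fell further in Hs578T (-3.04 ± 0.18) than in MDA-MB-231 (-0.65 ± 0.13), a difference of 2.39 ± 0.23. ANKRD1, a target of the growth regulator YAP, fell in Hs578T from 2.43 to 0.418 CPM and rose in MDA-MB-231 from 132 to 161 CPM, a difference of 2.80 ± 0.32. ICOSLG, a ligand of the T cell receptor ICOS, fell from 29 and 23 counts to 3 and 1 in Hs578T and from 15.7 to 11.4 CPM in MDA-MB-231, a difference of 3.05 ± 0.50. Among all genes tested, 2425 passed, with the effect more positive in Hs578T for 1525 and in MDA-MB-231 for 900, while DESeq2 called 1157 and leaving out MDA-MB-231 siGPX1 replicate 1 gave 1507.

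Of the other named differences, 4 rest on a few counts and 1 on a single library. PCDH1 had 2 and 4 counts in the Hs578T controls and 0 in both depleted libraries, 1.86-fold lower against the floor, and 14.7 and 22.8 CPM in MDA-MB-231. MBP had 0 counts in the Hs578T controls and 4 and 1 after depletion, 1.83-fold higher against the floor. TMLHE had 3 and 3 counts in the MDA-MB-231 controls and 0 after depletion, 1.88-fold lower against the floor. These folds set a group at 0 to a floor of 3 counts over the group. They leave out counting error in the other group, so with so few counts they are not firm lower bounds. ACVR1C had 1 and 2 counts in the MDA-MB-231 controls and 12 and 11 after depletion, and was at 5.77 and 5.92 CPM in Hs578T. DYX1C1-CCPG1, a read-through transcript and therefore uncertain, had 0 and 60 counts in the MDA-MB-231 controls and 0 after depletion. All 10 named differences had an adjusted p of at most 0.0465 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The balance of the 2425 calls depended on the scaling, since 37.1% were more positive in MDA-MB-231 with TMM factors and 55.6% of the calls were with DESeq2 size factors in the same edgeR test (58.3% with DESeq2 and 53.5% with limma on TPM values).

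G2/M genes differed most consistently between the lines. The depletion effect was more positive in MDA-MB-231 for 30 of 37 members and less positive for 0 (32 and 0 adjusted over the list alone), with a median difference of 0.35 and with MKI67 (0.77 ± 0.05), CDC20 (0.78 ± 0.06), CENPF (0.60 ± 0.05) and AURKA (0.61 ± 0.06) as examples. Camera with Benjamini-Hochberg adjustment gave adjusted p = 2.16e-17, and adjusted p = 0.485 with an estimated correlation. Hypoxia and glycolysis genes went the other way. The effect was more positive in Hs578T for 13 of 26 hypoxia genes and for 12 of 20 glycolysis genes, and in MDA-MB-231 for 0 of either (16 and 14, and again 0, adjusted over the list alone), with VEGFA at -1.22 ± 0.05, ADM at -1.33 ± 0.10, the glucose transporter SLC2A1 at -0.88 ± 0.05 (control-matched) and GPI at -0.50 ± 0.05. Camera gave adjusted p = 5.7e-06 and 0.00111, and adjusted p = 0.485 with an estimated correlation for each. Interferon-induced genes were more positive in MDA-MB-231 for 10 of 38 and in Hs578T for 2 (11 and 2 adjusted over the list alone), including PARP14 (0.57 ± 0.05) and TRIM22 (1.28 ± 0.21), with camera adjusted p = 6.1e-04 and adjusted p = 0.485 with an estimated correlation.

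Another 4 lists passed the interaction test and were each lost without at least 2 of the 8 libraries taken singly and with the replicate block (adjusted p from 0.0527 to 0.0958 by camera with Benjamini-Hochberg adjustment). Of 70 ribosomal protein genes, 12 were more positive in MDA-MB-231 and 1 in Hs578T (13 and 1 adjusted over the list alone), with RPL8 at 0.62 ± 0.05 (camera adjusted p = 0.0206, adjusted p = 0.764 with an estimated correlation, highest adjusted p = 0.265 without a library). Of 5 metallothioneins, 2 were more positive in MDA-MB-231 and 0 in Hs578T (2 and 0 adjusted over the list alone), namely MT2A (0.73 ± 0.05) and MT1E (0.82 ± 0.14), with camera adjusted p = 0.0206, adjusted p = 0.485 with an estimated correlation and a highest adjusted p of 0.0999 without a library. Of 33 genes of apoptosis and cell death, 8 were more positive in Hs578T and 1 in MDA-MB-231 (12 and 1 adjusted over the list alone; camera adjusted p = 0.0493, adjusted p = 0.485 with an estimated correlation). They included TFRC (-0.50 ± 0.05) and ACSL4 (-0.47 ± 0.05), which serve iron uptake and fatty acid activation. Of 6 leukocyte markers, CD68, a lysosomal protein also made by other cells, was more positive in MDA-MB-231 (0.49 ± 0.08) and 0 were more positive in Hs578T (2 and 0 adjusted over the list alone; camera adjusted p = 0.0315, adjusted p = 0.485 with an estimated correlation), and the mean of the list, -0.05, had the opposite sign to its median, 0.41 (0.53 with CD74 set to the floor of 3 counts). Named members that passed here had an adjusted p of at most 0.00177 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

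**Figure D4:**
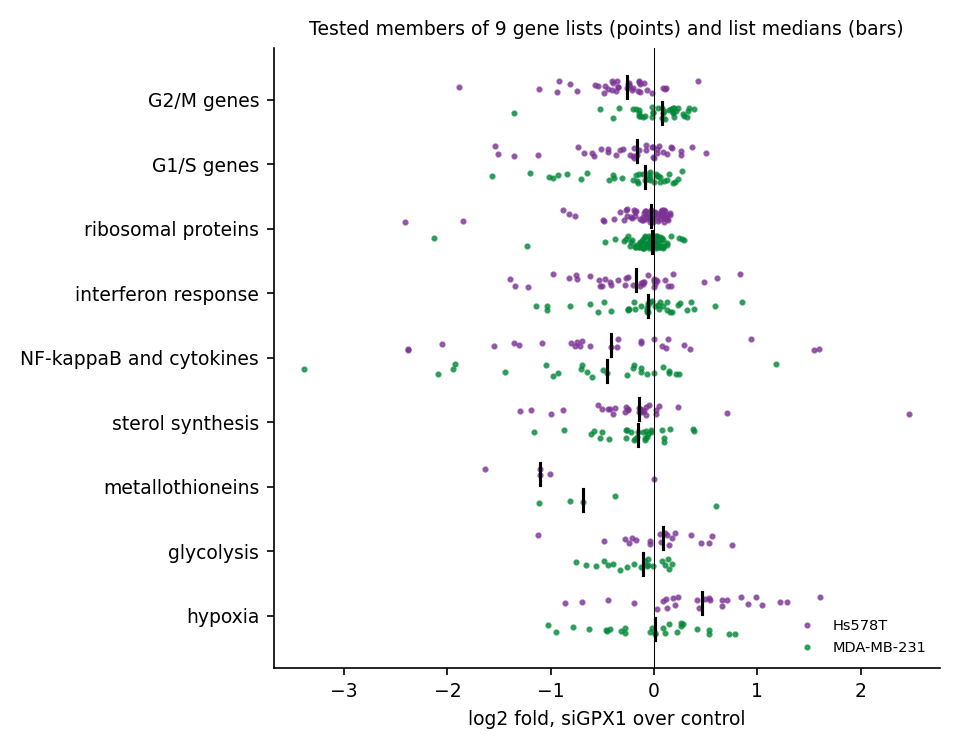
Log2 fold change of siGPX1 over control (horizontal axis) for the tested members of 9 gene lists (vertical axis), in Hs578T (purple) and MDA-MB-231 (green); points are genes and bars are list medians. The G2/M medians lie apart by line (-0.26 in Hs578T and 0.08 in MDA-MB-231), as do those of the hypoxia genes (0.46 and 0.01).

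The control libraries alone compared the lines without GPX1 depletion. CD74, the invariant chain of MHC class II, was at least 5182-fold higher in MDA-MB-231, HLA-DRA, an MHC class II chain, at least 2152-fold, and the growth factors TGFA and EREG at least 1332-fold and 758-fold. MBP, CALB2, CSF2RA and FLG were at least 1054-, 898-, 678- and 678-fold higher there. In Hs578T, the surface glycoprotein THY1 was at least 9460-fold higher, the collagen receptor ITGA11 at least 6831-fold, the prostacyclin synthase PTGIS at least 4840-fold, the mechanosensitive channel PIEZO2 at least 4457-fold, the cadherin CDH13 at least 3321-fold, the proteoglycan BGN at least 3218-fold and ITGA8 at least 3204-fold, against the same floor of 3 counts. POSTN, the matrix protein periostin, had 0 and 1 counts in MDA-MB-231 and 30109 and 28712 in Hs578T. All 16 had an adjusted p of at most 5.8e-15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the genes tested, 6122 were higher in MDA-MB-231 and 5507 in Hs578T, 2439 and 2649 of them over 2-fold.

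Extracellular matrix genes set the lines apart, with 35 of 41 higher in Hs578T and 6 higher in MDA-MB-231, and so did fibroblast markers, with 14 of 16 and 1. COL6A3 differed by -7.28 ± 0.06, SPARC by -11.76 ± 0.10 and COL1A1 by -8.79 ± 0.09 on the log2 scale (MDA-MB-231 over Hs578T), whereas S100A4, on the fibroblast list, was higher in MDA-MB-231 by 6.28 ± 0.07. Mesenchymal markers (16 of 22 higher in Hs578T, 4 in MDA-MB-231), targets of TGF-β (17 of 24 and 6), integrin and focal adhesion genes (22 of 35 and 9), ATF4 and unfolded protein response genes (28 of 36 and 8), NRF2 targets (16 of 24 and 5) and ribosomal protein genes (45 of 70 and 12) lay on the same side. Examples were the cadherin CDH2 (-9.34 ± 0.11), TGFBI (-4.74 ± 0.05, matched), ITGA5 (-2.49 ± 0.03), the serine synthesis enzyme PHGDH (-8.20 ± 0.10), AKR1C1 (-6.39 ± 0.12, matched) and RPL7 (-1.91 ± 0.05). Epithelial junction genes (20 of 24 higher in MDA-MB-231, 2 in Hs578T), apoptosis genes (26 of 33 and 4), G2/M genes (25 of 37 and 7) and histone genes (8 of 11 and 1) lay on the other, with the keratins KRT19 (10.52 ± 0.14), KRT7 (5.96 ± 0.08) and KRT8 (4.29 ± 0.06), PMAIP1 (2.32 ± 0.06), the cyclin CCNA2 (1.16 ± 0.05) and HIST1H2BK (3.04 ± 0.08) as examples. The counts adjusted over the list alone were the same for each of these 12 lists. Camera with Benjamini-Hochberg adjustment gave adjusted p from 3.78e-08 for the matrix genes to 0.0481 for the histone genes, which was lost with genes of either class of match and genes without a searched 3′ UTR set aside (adjusted p = 0.155), with TPM values (adjusted p = 0.0788) and with the replicate block (adjusted p = 0.0628), and adjusted p from 0.322 to 0.859 with an estimated correlation. Read lengths implied by the deposited effective lengths were 48.5 to 50.4 bases in Hs578T and 56.3 to 57.0 in MDA-MB-231, so any effect of read length cannot be separated from that of the line. Analysis of the TPM values shifted the median difference of all genes between the controls by 0.13 on the log2 scale.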

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

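The test of composition given here was chosen only after the result was seen. Everything listed in this part was brought up by the interaction test, that is, by a test of the difference in depletion effect between the lines. It passed for 900 genes with the effect more positive in MDA-MB-231 and for 1525 with the effect more positive in Hs578T, a balance that turned round with DESeq2 size factors. Among named genes the differences, as log2 change in MDA-MB-231 minus that in Hs578T, were 5.34 for PCDH1, 3.05 for ICOSLG, 2.88 for ACVR1C, 2.80 for ANKRD1 and 2.39 for CX3CL1 on one side, and -7.85 for DYX1C1-CCPG1, -4.67 for MBP, -4.65 for TMLHE, -2.88 for IL6 and -2.86 for SCG2 on the other. PCDH1, MBP, TMLHE and DYX1C1-CCPG1 had a group at 0 counts, so their fitted values are no bounds. Lists that passed had median differences of 0.35 for G2/M genes, 0.15 for interferon-induced genes, 0.73 for metallothioneins, 0.41 for leukocyte markers and 0.02 for ribosomal protein genes (0.0235 unrounded), and of -0.29 for hypoxia genes, -0.25 for glycolysis genes and -0.14 for apoptosis genes, each with an adjusted p of at least 0.485 with an estimated correlation by camera. All 8 medians kept their sign under other scalings, but with DESeq2 size factors and with TPM values that of ribosomal protein genes was 0.08 and 0.08, that of apoptosis genes -0.08 and -0.04 and that of glycolysis genes -0.19 and -0.16. With groups of 0 counts set to the floor, the apoptosis median was -0.11 and the leukocyte median 0.53.

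The difference in G2/M genes, which fell in Hs578T and did not pass as a list in MDA-MB-231, was weighed further. FN1 and a few other transcripts took a larger share of the counts in depleted Hs578T, but with total-count scaling and the 10 most abundant genes removed (2.31 to 10.3% of counts) the median difference was 0.39, against 0.41 before, while that of all tested genes was -0.01. A single divergent library is argued against as well, since the median stayed between 0.31 and 0.46 when each of the 8 was left out. Matches to the GPX1 sequence in the 3′ UTRs of these genes were held by 1 member, KIF2C, and the other 36 had a median of 0.34. No biological explanation was tested, and a difference between the lines themselves, culture density and the time of harvest, of which the labels give only the line, stay open. Action of an siRNA through shorter matches or through matched genes stays open too, as does that of any control siRNA, since only KIF2C was set aside.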

How the results depend on the processing

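The run without genes that hold a 3′ UTR match was chosen only after the results were seen, and all other alternatives were planned. GPX1 stayed between -4.64 and -4.51 in Hs578T and between -4.84 and -4.73 in MDA-MB-231 on the log2 scale. Over the calls of all named genes, 6301 of 6526 values kept their direction and side of the threshold, 217 were weaker, 8 stronger and 0 reversed. Values without an adjusted p under an alternative were left out. Most named genes were picked from these same libraries by size of change or smallest p, so this share does not describe calls in general. Testing against a fold of 1.5, a stricter question by construction, left 515 rises and 688 falls in Hs578T, 158 and 521 in MDA-MB-231, 99 and 364 in both lines, 91 differences between the lines, and 3290 and 3257 genes higher in MDA-MB-231 and Hs578T controls. DESeq2 called 1835 falls in MDA-MB-231, all of them among the 3115, and 1157 differences between the lines, 1123 of them among the 2425, and the cause was not tested. Without genes that hold a match or lack a searched 3′ UTR, 1325 genes fell in both lines, 1324 of them among the 2033, with fewer genes tested.

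With each library left out, falls in MDA-MB-231 ranged from 2037 (without its siGPX1 replicate 1) to 3324 and differences between the lines from 1507 (without the same library) to 2734. The lone library left in a group was assumed to vary like the others. Lists that passed ranged from 1 to 2 in MDA-MB-231 and from 5 to 10 for the interaction. An estimated correlation left 0 lists in Hs578T, 0 in MDA-MB-231 and 0 for the interaction, and fry, which asks another question, passed 22 in Hs578T and 17 in MDA-MB-231. The estimated correlation also left 0 in the controls, where the matrix genes had adjusted p = 0.441 by camera, so a list that fails it may still have moved. Camera on log2(TPM + 1) passed 2 lists in MDA-MB-231, the epithelial junction genes being added, and for the interaction the stricter filter left 5 and the replicate block 4. For these the cause was not tested. Deviations of libraries of the same replicate number correlated across genes by -0.0348 in Hs578T and 0.0558 in MDA-MB-231. Pairing was not tested, and with 2 libraries per group these values cannot show that it was absent. Fitting each line alone gives no value for the interaction or the controls. Depth limits the folds of genes with a few counts, such as PCDH1, MBP and TMLHE. Their interaction calls, and that of DYX1C1-CCPG1, whose 60 counts lie in 1 of 2 replicates, were each lost under at least 1 alternative.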

Other observations

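The search of 3′ UTRs and the luciferase test in this part were chosen only after the fold changes had been seen. Other selenoprotein genes moved in both directions after GPX1 depletion. Of 19 selenoprotein genes, 5 rose and 6 fell in Hs578T and 3 rose and 7 fell in MDA-MB-231. The list passed in neither by camera (adjusted p = 0.582 and 0.586 with Benjamini-Hochberg adjustment), whereas fry passed it downward in both (adjusted p = 3.96e-04 and 0.00203). TXNRD1, the cytosolic thioredoxin reductase, fell by 1.55 ± 0.04 and 1.02 ± 0.03 on the log2 scale and SELT by 0.66 ± 0.06 and 0.72 ± 0.06, both matched to GGGCATC or GGCATCA, while the lipid peroxidase GPX4 did not pass (-0.08 ± 0.04 and 0.02 ± 0.04). Of 24 NRF2 targets, 9 rose and 4 fell in Hs578T and 11 rose and 1 fell in MDA-MB-231 (adjusted p = 0.501 and 0.0752 by camera, the latter 0.0471 without either Hs578T siGPX1 library), among them the NADPH producer PGD (0.97 ± 0.06 and 0.73 ± 0.06), the sulfiredoxin SRXN1 (0.76 ± 0.05 and 0.37 ± 0.05) and FTL, the ferritin light chain (0.48 ± 0.04 and 0.29 ± 0.04). Catalase (CAT) fell in Hs578T (-0.35 ± 0.05) and rose in MDA-MB-231 (0.19 ± 0.05), a difference with adjusted p = 1.8e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

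Junction, mesenchymal, focal adhesion and protease genes were tested as separate lists, and none passed by camera in either line, whereas fry passed epithelial junction genes (adjusted p = 0.00104 in Hs578T and 0.00216 in MDA-MB-231), matrix proteases (adjusted p = 3.96e-04 and 0.00229) and, in Hs578T, focal adhesion genes (adjusted p = 0.0285, and 0.0607 in MDA-MB-231), each upward. Among 24 epithelial junction genes, 9 rose and 1 fell in Hs578T and 13 rose and 2 fell in MDA-MB-231 (adjusted p = 0.41 and 0.0752 by camera with Benjamini-Hochberg adjustment, the latter 0.0456 with TPM values), with the keratin KRT18 at 1.62 ± 0.05 and 0.65 ± 0.05 and the desmoglein DSG2 at 0.49 ± 0.04 and 0.43 ± 0.04. Among 22 mesenchymal markers, 9 rose and 8 fell in Hs578T and 5 and 5 in MDA-MB-231 (adjusted p = 0.747 and 0.586 by camera), with the receptor kinase AXL lower by 1.33 ± 0.03 and 0.57 ± 0.03 and vimentin (VIM) higher by 0.25 ± 0.03 and 0.35 ± 0.03. Of 35 integrin and focal adhesion genes, 14 rose and 8 fell in Hs578T and 13 and 8 in MDA-MB-231 (adjusted p = 0.75 and 0.466 by camera), with PXN 2.83-fold and 2.36-fold higher and ACTN1 lower by 0.71 ± 0.04 and 0.85 ± 0.04. Of 26 matrix protease genes, 12 rose and 6 fell and 12 rose and 5 fell (adjusted p = 0.457 and 0.221 by camera), and TIMP2, an inhibitor of these proteases, fell by 1.44 ± 0.05 and 1.07 ± 0.05 (matched). Outside these lists, the autophagy receptor SQSTM1 fell by 1.92 ± 0.03 and 1.45 ± 0.03 (matched), and UQCRH, of respiratory complex III, fell by 2.08 ± 0.07 and 1.85 ± 0.07 and holds the full GGGCATCA.

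Genes that fell in both lines were weighed against the silencing of unintended targets through seed matches, in which 7 bases of an siRNA pair with a 3′ UTR. Of the 10 sequences of 7 bases with the most negative association, 4 lie in the GPX1 transcript in sense orientation and passed Bonferroni adjustment in both lines. They are overlapping windows within 10 bases and count as 1 match, and 7.99% of all sequences searched lie in that transcript. The match is consistent with a GPX1 siRNA that acts on MDH2, CLCN4, TMEM64 and other matched genes. Genes without the matches fell in both lines 3.14 times as often as chance overlap gives (1337 against 426). For genes without any 6 bases of the site anywhere in the transcript the ratio was 4.39 (127 against 28.9), and for matched genes 1.80 (634 against 352). The classes cannot be ranked by these ratios, since the more genes of a class are called, the lower its largest possible ratio. Of 1822 matched genes, 797 fell in Hs578T and 804 in MDA-MB-231. Of 2549 genes without the 6 bases, 275 and 268 fell. These ratios do not decide whether seed matches were the whole cause. The chance count treats every gene as equally likely to be called, and genes that respond to a matched gene could fall in both lines too. Shorter matches also went with lower expression. GGCATCT, which shares 6 bases with the site, ranked 3 (Bonferroni-adjusted p = 1.47e-43 in Hs578T and 2.25e-51 in MDA-MB-231 from linear models across genes). For genes without the 7-base matches, ADIPOR2 and BAG2 among them, several accounts stay open. They are a response to GPX1 loss, action of the same siRNA through shorter matches or through matched genes, a shared effect of transfection and effects of another siRNA. A second siRNA would bear on effects of the siRNA sequence, and GPX1 restored from a resistant copy on a response to GPX1 loss.

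Genes that rose in both lines were weighed against release from a control siRNA or from microRNAs, which would leave higher levels of genes with its seed matches. The sequence with the most positive association passed Bonferroni adjustment in both lines, with a larger p of 0.00303 and a smaller one of 3.89e-06 from linear models across genes, which fits release for control-matched genes such as SOX4, CDC42SE2 and TATDN3. A control siRNA against luciferase GL2 was also looked at, with a target sequence taken from general knowledge and not from the series. Of the 5 sequences with the most positive association, 2 lie in its strands, against 0.129% of all sequences searched, but they overlap by 6 bases and the target was looked up only after they were seen. The match therefore decides nothing, and the labels do not name the control. Genes without these matches rose in both lines 2.45 times as often as chance overlap gives (1977 against 807). That ratio does not decide whether release was the whole cause. The chance count treats every gene as equally likely to be called, and only genes with ACTTCGA or TACTTCG were set aside, so other microRNA matches were not covered. ARL6IP1, CLDN12, CPOX, EFR3A, INPP5A and CAV2 are among the large rises without ACTTCGA or TACTTCG.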
